A study of Zea mays with 62 samples.

How the data were processed

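The series holds 62 maize samples in 19 groups of tissue, side and time. Per the labels, plants of line O9B were grown in a glasshouse. At 60 to 65 days from sowing, when the primary cob tip showed, they were laid on the floor at about 20 degrees. Pulvini were dissected and frozen, and messenger RNA was isolated from total RNA, amplified and labelled with Cy3 or Cy5. The labels speak of 108 samples, of which only the 62 deposited here were analysed. Titles that name neither side were taken as controls, since the design text of the series describes controls that did not bend; the titles themselves do not say so. The labels state no link between samples of the same replicate number. Residuals of samples with the same number in groups of the same tissue and time correlated above 0.1 in 36 of 47 pairs, with r from −0.34 to 0.59 and a median of 0.23. In 6 comparisons with at least 3 such pairs every pair exceeded 0.1, so there the numbers were taken to pair the samples, on the evidence of the data alone. They were stem lower with upper at 1 h, r from 0.41 to 0.54, and at 6 h, 0.14 to 0.56, and leaf sheath lower with upper at 6 h, 0.36 to 0.59. The others were lower with control in the stem at 1 h, 0.19 to 0.43, and in the leaf sheath at 1 h, 0.36 to 0.55, and at 6 h, 0.13 to 0.54. Between tissues, the numbers were likewise taken to pair controls, r from 0.23 to 0.46 in 8 pairs. So they were for the sides at 1 h, 0.29 to 0.64 in 5 pairs, and at 24 h, 0.11 to 0.37 in 5 pairs. Of these, 6, 5 and 3 pairs shared an array, which by itself can give such a correlation. Lower and upper samples were also taken as pairs within the groups of 2 further tests. The difference of tissues at 6 h gave 0.14 to 0.59 in 7 pairs. The stem sides at 24 h less 1 h gave 0.11 to 0.54 in 5 pairs. Samples of different number were not compared in this way, and the numbers largely follow the 2 scan sessions given below. A link by number and a shared session thus cannot be told apart. Apart from shared arrays, the main fit did not model these pairs. A replicate block, with 1 effect per number shared by all groups, was fitted as an alternative.

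Per the file headers, each scanner file holds spot and local background intensities with no normalization, made by the scanner software. They also hold a processed signal, an intensity from which the software had subtracted background and removed spatial trends and which it had dye-normalized within the array, and flags of outliers, of saturation and of signal well above background. Both channels of each of 31 arrays on 16 slides were present. The authors' deposited table for the whole series holds 102961 rows and 105 columns, with a normalized intensity per sample whose scaling step the files do not state. The deposited ratio columns hold a ratio of group means to control or of lower to upper side. The deposited p-value columns give the authors' test of a side against control, and the deposited q value, a score for the false discovery rate, stands beside the p. Neither is given for the leaf sheath upper side at 1 and 6 h. How the authors made the p and q values is not stated in the files.

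Background was corrected on mean spot intensity and median background by normexp with an offset of 50 in limma 3.58.1 under R 4.3.3. Loess was fitted within each array with control spots given no weight, and Aquantile scaling was used between arrays, after which the channels were treated as single samples on the log2 scale. Spots with an outlier mark were left out, which left 690 missing values among tested probes, and spots of the same probe were averaged. Of 105010 spots, 1325 were controls. The remaining 103685 carried 103680 different probes. A probe was tested if it was well above background in all but 1, and in at least 2, of the samples of at least 1 group, which left 55376. Tables were read with data.table (version 1.17.8), and figures were drawn with matplotlib 3.10.9 and pandas 2.3.3.

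All samples were fitted together by limma with the 19 groups and the dye as fixed terms and the array as a random block. The correlation within arrays was 0.412, from 5000 probes drawn with a fixed seed and statmod 1.5.0. The prior degrees of freedom were 1.98. Dye was not balanced over groups: 21 leaf sheath samples carried Cy3 and 8 Cy5, and 10 stem samples carried Cy3 and 23 Cy5. Leaf sheath lower and upper sides at 1 h and the upper side at 24 h carried Cy3 alone. Stem upper side at 1 h and stem controls at 6 h carried Cy5 alone. The 27 contrasts were tested with limma's moderated statistic, two-sided, and adjusted by the Benjamini-Hochberg method over the probes of each contrast, at a threshold of 0.05. Adjustment was not made over contrasts. The root mean square log2 difference is the root of the mean of squared estimates less their squared standard errors, with a negative mean set to 0.

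None of the 103685 probe entries matched the gene table at hand. Of these, 68310 carried the probe ID alone, 34089 a contig name, with 4318 of them marked as reverse, and 1286 a clone or protein accession. The 33 gene lists fixed beforehand could therefore not be tested. Named probes followed a rule set before the data were examined: where probes have no gene names, at most 2 that rose and 2 that fell. They were the largest changes among calls whose samples did not overlap, 2 each way between lower and upper side and 1 each way elsewhere. Against a group in which no sample was well above background, the fold was taken from group means, open to dye bias. In each dim sample it takes the higher of the lowest value well above background and the probe's own. For P1000263010, the only such probe, its own value was the higher in all 3 samples, so the fold equals the ratio of the means. The fit gave a smaller fold, so that ratio is not a lower limit.

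The fit was tested on simulated data with 200 changed among 55376 probes. The simulated probes were independent and normal, with 1 spread per probe in all groups and the correlation within arrays. Pairs by replicate number and unequal spread of groups were left out, so the rates below hold only for data of that kind. For stem lower minus upper at 24 h, with 3 samples against 3, 59.7% of changes of 0.5 on the log2 scale were called, 86.6% of those of 1 and 98.5% of those of 2, with 6 false calls. For stem at 6 h, with 4 against 4, it was 64.2%, 95.5% and 100%, with 8 false calls. For leaf sheath at 1 h, with 3 against 2, it was 47.8%, 77.6% and 98.5%, with 5 false calls. For leaf sheath at 24 h it was 58.2%, 92.5% and 98.5%, with 6 false calls.

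Alternatives fixed before the data were examined were quantile normalization of single channels, the processed signal less its 75th percentile per channel, no filter, a replicate block, the slide as random block, no dye term, samples of the tissue alone, the deposited table, and each replicate left out in turn. The scanner files show 2 sessions. Session 1 held 32 samples, all of replicates 1 and 2, and session 2 held 30, those of replicates 3 and 4 and the array of both 24 h controls of replicate 2. Fits with session as a block and within each session were added after the data were seen. Each session held 1 or 2 samples per group, and a single sample was assumed to vary like the other groups. Shared responses of both sides were compared with simulated groups that had no change but the same shared controls. Their samples were drawn independently, with no correlation within arrays, no dye and no pairs by replicate number.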

Results

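Gene expression was measured in the pulvini of maize plants laid over so that they bent upward. Pulvini are the swollen joints at the base of leaf sheaths and on the stem in which a grass shoot bends. The series holds 62 samples, each 1 dye channel of a 2-colour Agilent array, from 31 arrays on 16 slides. The labels divide them into stem pulvini, 33 samples, and leaf sheath pulvini, 29 samples. Bending pulvini were separated into a lower and an upper side after 1, 6 or 24 h, and pulvini that did not bend served as controls. Stem controls were also taken at 0 h.

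Leaf sheath controls numbered 4 at 1 h, 4 at 6 h and 3 at 24 h. The leaf sheath lower side had 3 samples at each time, and the upper side had 2, 4 and 3. Stem controls had 3 samples at each of 0, 1, 6 and 24 h. The stem lower side had 4, 4 and 3 samples, and the upper side had 3, 4 and 3. The share of probes well above background ran from 26.7% of a sample to 55.7%, with a median of 43.8%. The dimmest sample was leaf sheath control 24 h replicate 1, at 26.7%, and stem lower 1 h replicate 3 came next at 27.4%. No sample had more than 3 saturated spots. Of 103680 probes that were not controls, 55376 were tested. The files do not pair the probes with gene names, so each comparison is given in counts of probes, with at most 2 probes that were higher and 2 that were lower. A probe is called when its adjusted p from limma is under 0.05. For each probe listed as among the largest changes of a comparison, the samples of the groups compared did not overlap. The number of arrays per group limits the precision of every value.

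Stem and leaf sheath samples separated along the principal component that held the most variance, 23.1% of it. All 29 leaf sheath samples scored from −72.7 to −2.55 on it and all 33 stem samples from 8.32 to 62.4. The next component held 15.2% and followed side and time within the stem. Stem controls had mean scores on it of 13.9 at 0 h, 39.1 at 1 h, 65.8 at 6 h and 45.3 at 24 h. Both stem sides lay well below their controls at 1 h, at −29.3 for the lower and −32.7 for the upper side. By 24 h the stem sides had moved apart, to −41.6 for the lower and 9.48 for the upper side. The leaf sheath lower side at 24 h had the lowest mean score of all 19 groups, −65.9 ± 9.71 (SD, n = 3). Correlation of log2 intensities across probes was 0.949 to 0.993 for the 73 pairs of samples within a group, with a median of 0.979. The median between groups was 0.946. Probes are not independent replicates.

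**Figure D1:**
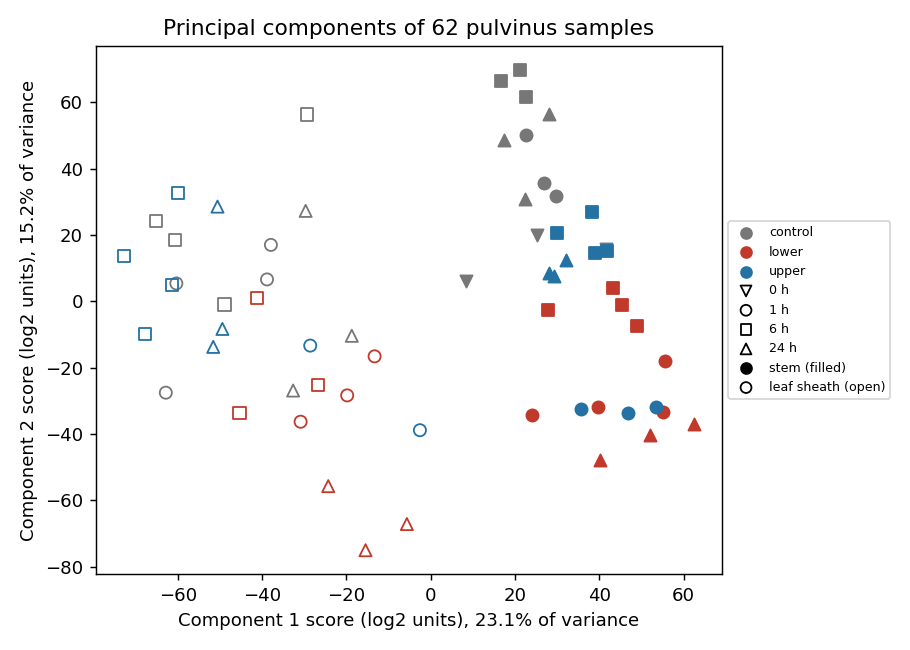
Scores of the 62 samples on the leading pair of principal components of log2 intensity, in log2 units; colour gives the side, shape the time and filling the tissue. Leaf sheath samples lie at −2.55 or below on component 1 and stem samples at 8.32 or above.

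The series compares the lower with the upper side of bending pulvini, to ask which transcripts differ across the bend. In the stem, more probes were called at each later time. Of 55376 probes, 845 were called at 1 h, of which 409 were higher in the lower and 436 higher in the upper side. At 6 h there were 2627 calls of 55375 probes, 1071 higher in the lower and 1556 higher in the upper side. At 24 h there were 6421, of which 3188 were higher in the lower and 3233 higher in the upper side. Changes of at least 2-fold made up 165 of the higher and 137 of the lower calls at 1 h, 284 and 183 at 6 h, and 624 and 749 at 24 h. The root mean square log2 difference, with the part due to noise taken off, was 0.15 at 1 h, 0.20 at 6 h and 0.33 at 24 h. With 1 library left out in turn it ran from 0.13 to 0.18, from 0.17 to 0.23 and from 0.30 to 0.35. The ranges at 1 h and 6 h overlap, and of these steps only 24 h against 1 h was tested.

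At 1 h the probe with the largest excess of the stem lower over the upper side was P1000295830. It measured 12.89 ± 1.22 (SD, n = 4) in lower and 8.02 ± 0.74 (SD, n = 3) in upper samples, 28.9-fold higher, with an adjusted p of 3.26e-08. P1000219221 was 19.5-fold higher in the lower side, with an adjusted p of 1.4e-06. P1000225510 was 9.34-fold and P1000225231 8.15-fold lower there, both with an adjusted p of 7.26e-10. The sequences of these 2 probes nearly match over most of their length, so they may not report separate transcripts. Both had risen on both sides over control at 1 h. P1000225510 was higher by a log2 change of 4.91 in the upper side and 1.69 in the lower side. At 6 h P1000211655 was 8.27-fold higher in the lower side, with an adjusted p of 8.03e-04, and P1000295264 7.01-fold higher, with 1.83e-05. P1000265381 was 7.58-fold lower, with an adjusted p of 1.88e-03, and P1000261994 6.91-fold lower, with 9.2e-05.

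At 24 h the probes with the largest stem differences were lower in the lower than in the upper side. P1000291405 measured 8.07 ± 0.55 (SD, n = 3) in lower and 14.47 ± 0.15 (SD, n = 3) in upper samples, 72.2-fold lower, with an adjusted p of 1.01e-07. P1000261994 was 59.4-fold lower, with an adjusted p of 9.55e-10. P1000235184 was 10.9-fold higher in the lower side, with an adjusted p of 1.04e-04, and P1000227495 9.94-fold higher, with 5.26e-04. Against control at 24 h, P1000261994 fell by 4.63 on the log2 scale in the lower side. Its upper side stood at a log2 difference of 1.26 from control, which did not pass the test. P1000291405 fell by 2.26 in the lower side and rose by 3.91 in the upper side.

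The stem counts depended on single libraries. Without upper replicate 2 there were 492 calls at 1 h, and without upper replicate 4 there were 549. Of all 35 ways to divide the 1 h samples into groups of 4 and 3, 3 gave 845 calls or more. The real division was 1 of these, and the highest gave 971. At 6 h there were 1563 without lower replicate 1, 1750 without upper replicate 2 and 1465 without upper replicate 4. The 24 h count was 3309 without lower replicate 4, 3353 without upper replicate 1 and 3828 without upper replicate 2. The arrays were scanned in 2 sessions, and the counts within session 1 were 183 at 1 h, 769 at 6 h and 1034 at 24 h. Within session 2 they were 73, 13 and 129. Of the session 1 calls, 97.8%, 96.0% and 88.9% had the same direction in session 2. Quantile normalization turned the split at 6 h to 876 higher and 795 lower. The deposited table turned the split at 24 h to 1788 higher and 3189 lower.

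The leaf sheath sides differed little at 1 h and more than the stem at 24 h by count of calls. At 1 h, 30 probes were called, 10 higher in the lower and 20 higher in the upper side, with 1772 at an unadjusted p under 0.05. At 6 h there were 4872 calls, 2474 higher in the lower and 2398 higher in the upper side. At 24 h there were 12350, of which 6197 were higher in the lower and 6153 higher in the upper side, or 22.3% of all probes tested. Calls of at least 2-fold numbered 592 higher and 295 lower at 6 h, and 1222 and 993 at 24 h. The root mean square log2 difference was 0.27 at 6 h and 0.41 at 24 h. At 1 h it was set to 0, since the squared estimates were on average no larger than their squared standard errors. With 1 library left out it ran from 0.23 to 0.30 at 6 h and from 0.37 to 0.46 at 24 h.

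Probe P1000295264 was higher in the leaf sheath lower side already at 1 h, at 12.67 ± 0.54 (SD, n = 3) against 9.56 ± 0.29 (SD, n = 2), 8.53-fold, with an adjusted p of 3.26e-02. It was called higher in the lower side at all 3 times in both tissues, with log2 differences from 1.97 to 3.09. P1000286553 was 6.94-fold higher at 1 h, with an adjusted p of 4.8e-02. Its means lay close to those of P1000295264 in every group, and whether the probes report separate transcripts is not known. P1000214226 was 3.12-fold lower, with 8.59e-04, and P1000211435 16-fold lower, with 3.26e-02. The last of these rests on 1 upper sample, replicate 2, at 15.23, beside 7.85 in the other. Without that sample its log2 difference was −0.99, with an adjusted p of 1.00. The call of P1000295264 was lost without lower replicate 1 or 2 or upper replicate 2 or 4, with adjusted p from 0.139 to 0.344. The call of P1000286553 was lost without any of the 5 samples, with adjusted p from 0.0760 to 0.605. That of P1000211435 was also lost without lower replicate 1, 2 or 4, with adjusted p of 0.122, 0.143 and 0.0702. With the processed signal none of these 4 probes was called, with adjusted p from 0.0601 to 0.648. With no filter P1000295264 and P1000211435 had an adjusted p of 0.0616 and P1000286553 one of 0.0763. With leaf sheath samples alone P1000286553 had 0.0809 and P1000211435 0.271. P1000286553 also lost its call with no dye term, at 0.0545, and with scan session as a block, at 0.0513.

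At 6 h P1000252345 was 16.1-fold higher in the leaf sheath lower side, with an adjusted p of 1.09e-06, and P1000304780 15.2-fold higher, with 1.95e-05. P1000261994 was 14.6-fold lower, with an adjusted p of 2e-06, and P1000291405 9.9-fold lower, with 7.3e-04. At 24 h P1000310970 was 22.8-fold higher, with an adjusted p of 2.25e-06. P1000244405 was 19.6-fold higher, with 1.13e-08, at 12.39 ± 0.75 (SD, n = 3) against 7.64 ± 0.32 (SD, n = 3). P1000261994 was 24.6-fold lower, with an adjusted p of 5.13e-08, and P1000271102 21.3-fold lower, with 1.39e-03. P1000261994 thus was lower in the lower side at 6 h and 24 h in both tissues.

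The leaf sheath 1 h count was 5 without lower replicate 1, 4 without lower replicate 2, 8 without lower replicate 4, 10 without upper replicate 4 and 58 without upper replicate 2. Where a single sample stayed in a group, also within a scan session, it was assumed to vary like the other groups. The 6 h count was 1855 without lower replicate 4, and the 24 h count was 8169 without upper replicate 3. Within session 1 there were 8, 438 and 171 calls at 1, 6 and 24 h, and within session 2 there were 18, 907 and 4692. Of the session 1 calls, 75%, 99.8% and 99.4% had the same direction in session 2. Across all probes the correlation between sessions was −0.04 at 1 h, 0.69 at 6 h and 0.75 at 24 h. The 1 h split was 32 higher and 36 lower with quantile normalization, 13 and 3 with the processed signal, and 9 and 2 with the deposited table.

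**Figure D2:**
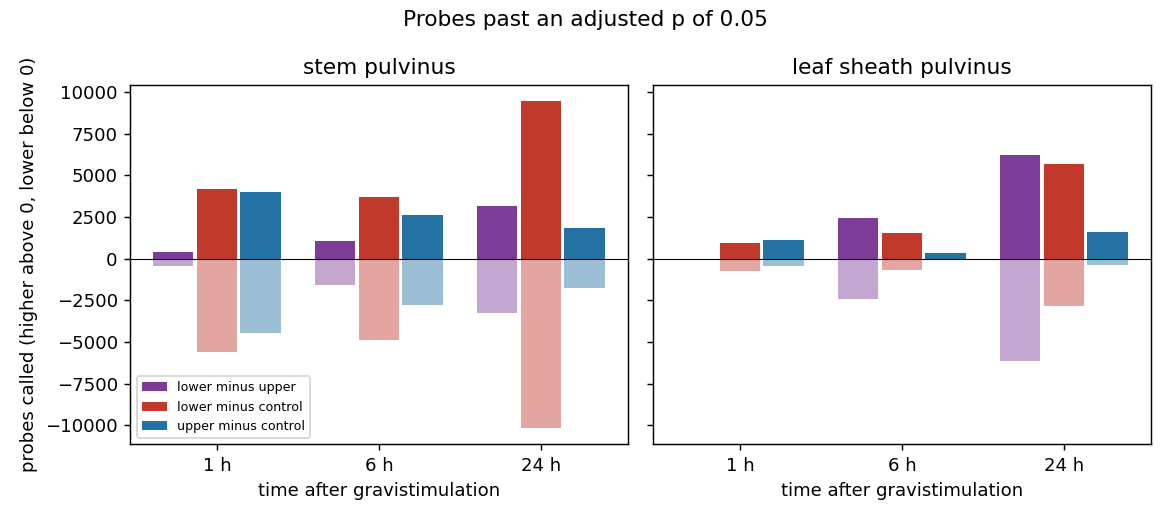
Probes past an adjusted p of 0.05 in each comparison of sides, by time, for stem and leaf sheath; bars above 0 count probes higher in the side named before "minus" and bars below 0 count probes lower in it. Lower minus upper rose from 845 to 6421 calls in the stem and from 30 to 12350 in the leaf sheath.

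Each bending side was next compared with pulvini that did not bend at the same time. On the stem lower side 9794 probes were called at 1 h, 4206 higher and 5588 lower than control. There were 8574 at 6 h, 3697 higher and 4877 lower, and 19600 at 24 h, 9449 higher and 10151 lower. On the stem upper side there were 8460 calls at 1 h, 3991 higher and 4469 lower. The upper counts were 5405 at 6 h, 2604 higher and 2801 lower, and 3601 at 24 h, 1846 higher and 1755 lower. The root mean square log2 difference from control was 0.38, 0.37 and 0.46 in the stem lower side and 0.40, 0.28 and 0.24 in the upper side at the 3 times.

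P1000287201 had the largest rise over control on both stem sides at 1 h. It measured 14.76 ± 0.29 (SD, n = 4) in the lower side, 15.20 ± 0.47 (SD, n = 3) in the upper side and 7.74 ± 1.06 (SD, n = 3) in controls. That was 144.5-fold higher in the lower side, with an adjusted p of 1.05e-13, and 172.2-fold higher in the upper side, with 5.96e-13. In the leaf sheath it was higher by a log2 change of 3.12 and 2.15. P1000259002 was 6.47-fold lower in the stem lower side, with an adjusted p of 1.01e-04, and 7.73-fold lower in the upper side, with 9.93e-05. At 6 h P1000264979 was 38.9-fold higher in the stem lower side, with 1.86e-08, and P1000218755 28.6-fold higher in the upper side, with 3.41e-04. P1000296268 was lower at 6 h on both sides, 6.9-fold and 5.5-fold. At 24 h P1000234622 was 22.8-fold higher in the lower side, with an adjusted p of 1.14e-07. P1000305999 was 21.3-fold higher in the upper side, with 8.32e-15, and P1000279447 6.37-fold lower, with 2.91e-03. P1000305999 measured 12.03 ± 0.10 (SD, n = 3) in the upper side and 7.51 ± 1.21 (SD, n = 3) in controls, 2 of them well above background. Its adjusted p rests on the spread over all 19 groups, among them stem controls at 6 h with an SD of 0.01, and not on these controls alone.

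Single control libraries moved the stem counts. Without control 1 h replicate 3 there were 5427 calls for the lower and 5422 for the upper side at 1 h. Without control 6 h replicate 3 there were 5244 and 2564, and without upper replicate 4 there were 3343 for the upper side. Without control 24 h replicate 4 there were 9459 and 1461. The lower count at 24 h was 10578 without lower replicate 4. The upper count at 24 h was 2372, 1815 and 1637 without upper replicates 1, 2 and 3. Within session 1 the lower side gave 1873, 4370 and 1310 calls and the upper side 3614, 809 and 16. Within session 2 they gave 1760, 103 and 11788, and 868, 0 and 63. The upper side at 6 h, with 0 calls from limma within session 2, had 3520 probes there at an unadjusted p under 0.05. Of the session 1 calls, 92.3% to 99.5% had the same direction in session 2. The upper split was 2302 higher and 1058 lower at 6 h and 1346 and 636 at 24 h with the processed signal. With the deposited table it was 4591 and 3324 at 1 h, 1531 and 712 at 6 h, and 603 and 354 at 24 h.

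In the leaf sheath fewer probes were called against control than in the stem. The lower side gave 1693 calls at 1 h, 962 higher and 731 lower, and 2193 at 6 h, 1516 higher and 677 lower. At 24 h it gave 8484, 5671 higher and 2813 lower. The upper side gave 1577 calls at 1 h, 1127 higher and 450 lower, and 397 at 6 h, 338 higher and 59 lower. At 24 h it gave 1985, 1583 higher and 402 lower. The root mean square log2 difference was 0.21, 0.23 and 0.36 for the lower side and 0.22, 0.12 and 0.22 for the upper side. Whether stem and leaf sheath differed in their change from control was not tested.

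P1000279134 had the largest rise on both leaf sheath sides at 1 h, 22.5-fold in the lower side, with an adjusted p of 3.47e-07, and 35.7-fold in the upper side, with 4.85e-07. In the stem at 1 h its log2 changes were 6.81 and 6.41. P1000280975 was 5.9-fold lower in the lower side, with an adjusted p of 1.39e-02, and 7.57-fold lower in the upper side, with 1.25e-02. At 6 h P1000304780 was 20.1-fold higher in the lower side, with 1.05e-05, and P1000231378 5.16-fold lower, with 9.42e-03. P1000261994 was 8.18-fold higher in the upper side at 6 h, with an adjusted p of 9.58e-04, and P1000298693 2.46-fold lower, with 3.26e-02. At 24 h P1000244405 was 17.7-fold higher in the lower side, with 1.7e-07, and P1000233333 10.1-fold lower, with 3.7e-03. P1000239748 was 7.43-fold higher in the upper side, with 3.69e-05, and P1000235012 5.82-fold lower, with 5.45e-03.

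Several of these leaf sheath calls were lost without 1 library. P1000280975 had an adjusted p of 0.0599 and 0.0776 for the lower side without lower replicates 1 and 2, and 0.679 for the upper side without upper replicate 4. P1000231378 had 0.0591 without lower replicate 4, and P1000235012 0.0553 without control replicate 3. P1000298693 had 0.0579 to 0.200 without control replicate 1, 2 or 4 or upper replicate 1, 2 or 3, 0.0535 with no filter and 0.0879 with leaf sheath samples alone. The upper side call of P1000280975 was also lost with quantile normalization, at an adjusted p of 0.0761, and with the processed signal, at 0.128. Counts moved as well. The lower side at 1 h gave 1050 and 468 calls without control replicates 2 and 3, and 490 and 546 without lower replicates 1 and 2. At 6 h it gave 1435 and 656 without lower replicates 2 and 4. At 24 h it gave 5493, 5600 and 5381 without control replicate 2 and lower replicates 1 and 3. The upper side at 1 h gave 877 without control replicate 3 and 52 without upper replicate 4. At 6 h it gave 86 and 124 without control replicates 2 and 4, and 108 and 163 without upper replicates 2 and 3. At 24 h it gave 766 without control replicate 3 and 776 without upper replicate 3.

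Within session 1 the leaf sheath lower side gave 82, 544 and 2201 calls against control, and within session 2 it gave 14, 243 and 2877. The upper side gave 16, 31 and 5, and 595, 2 and 184. Of the session 1 calls, 80% to 98.8% had the same direction in session 2. Other scalings moved the split of the lower side at 1 h to 1163 higher and 1438 lower with quantile normalization, 1325 and 1704 with the processed signal, and 11285 and 4134 with the deposited table. That table moved the median of all probes in this comparison by 0.34 on the log2 scale. The lower split at 24 h was 3998 and 3684 with the processed signal and 3753 and 3222 with the deposited table. The upper split was 341 and 227 at 1 h and 540 and 283 at 24 h with the processed signal. It was 150 and 58 at 6 h with quantile normalization, and 280 and 125 at 24 h with the deposited table.

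Which side had moved from control was then counted for each probe called between sides; these comparisons share the samples of the bending sides. In the stem at 24 h, 88.8% of the 3188 probes higher in the lower side were called higher than control in that side and not lower in the upper side. A call of lower in the upper side and not higher in the lower side was made for 1.6% of them. Below, a probe called only in 1 side was not called in the opposite direction in the other, where it may have moved the same way. A probe called in neither may still have been called in a direction that was not counted. Of the 3233 probes higher in the upper side, 71.1% were called only as lower than control in the lower side, and 12.6% only as higher in the upper side. At 1 h, 80.7% of the 409 probes higher in the stem lower side were called only as higher than control there. Of the 436 probes higher in the upper side at 1 h, 94.0% were called only as higher than control in the upper side. Their median log2 difference from control was 1.05 in the upper and 0.31 in the lower side. At 6 h, 74.8% of the 1071 stem probes higher in the lower side were called only as higher there. Of the 1556 higher in the upper side, 42.2% were called only as lower in the lower side, 27.8% only as higher in the upper side, and 29.8% in neither. For the leaf sheath at 6 h, 51.5% of the 2474 probes higher in the lower side and 75.1% of the 2398 higher in the upper side were called in neither. At 24 h, 59.4% of the 6197 leaf sheath probes higher in the lower side were called only as higher there, 2.6% only as lower in the upper side, and 37.6% in neither. Of the 6153 probes higher in the leaf sheath upper side, 27.5% were called only as lower in the lower side, 15.3% only as higher in the upper side, and 56.4% in neither.

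Both stem sides moved in the same direction from control at 1 h. Among probes called higher, 2594 were shared by the lower and upper sides, against 303.1 expected of independent lists. Among those called lower, 3278 were shared, against 451 expected. Because both sides were compared with the same control samples, some agreement arises without any response. The correlation of log2 differences across probes was 0.85 at 1 h, 0.80 at 6 h and 0.64 at 24 h in the stem. Simulated groups with no change and independent samples gave 0.53, 0.57 and 0.51. In the leaf sheath it was 0.80 at 1 h, 0.20 at 6 h and 0.19 at 24 h, against 0.37, 0.46 and 0.50 simulated. With different control samples for each leaf sheath side, the correlation was 0.64 at 1 h and −0.07 at 6 h. Probes are not independent replicates here either.

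Stem controls of different times were compared to show what changed without bending. At 1 h against 0 h, limma called 2 probes, with 5500 at an unadjusted p under 0.05. P1000306070 was 1.66-fold higher at 1 h and P1000229063 1.36-fold higher, both with an adjusted p of 0.0463; the latter is named only because so few were called. At 6 h it called 4034, of which 2896 were higher and 1138 lower. P1000298917 was 23.7-fold higher at 6 h, with an adjusted p of 5.68e-14, and P1000211294 39.1-fold lower, with 2.66e-06. At 24 h against 0 h there were 2182 calls, 1990 higher and 192 lower. P1000263010 was well above background in no 0 h sample, at a mean of 6.52 ± 0.04 (SD, n = 3), and in 2 of 3 samples at 24 h, at 9.83 ± 2.83 (SD, n = 3). The ratio of these means was 9.93-fold. The fit itself estimated 5.83-fold, with an adjusted p of 4.18e-02, so 9.93-fold is not a lower limit. P1000291252 was 3.97-fold lower at 24 h, with 4.19e-02. The series holds no leaf sheath sample at 0 h.

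The 1 h control count from limma was 0, 14 and 1 without 0 h replicates 1, 2 and 4, and 11, 0 and 0 without 1 h replicates 1, 2 and 3. The counts of 0 had 5103, 5432 and 2956 probes at an unadjusted p under 0.05. The call of P1000306070 was lost without 0 h replicate 1 or 4 or any 1 h replicate, with adjusted p from 0.0692 to 0.439. The 6 h count was 2464 without 0 h replicate 4 and 1904 without 6 h replicate 3. The 24 h count was 968, 857 and 1024 without 0 h replicates 1 and 2 and 24 h replicate 4. P1000263010 lost its call without any 0 h replicate or 24 h replicates 2 or 4, with adjusted p from 0.0692 to 0.364. P1000291252 lost its call without any 0 h or 24 h replicate, with adjusted p from 0.0551 to 0.251. It also lost it with quantile normalization, no filter, a replicate block or no dye term, with adjusted p from 0.0538 to 0.104. P1000263010 also lost it with the processed signal, no filter or stem samples alone, with adjusted p from 0.0728 to 0.126, and P1000306070 with no filter, no dye term or stem samples alone, from 0.0551 to 0.0848. Within session 1 limma made 0, 523 and 16 calls, the 0 with 1727 probes at an unadjusted p under 0.05, and within session 2 it made 3, 123 and 2. Of the session 1 calls at 6 h, 98.3% had the same direction in session 2, but of the 16 at 24 h, 37.5% had. With the processed signal the split was 2132 higher and 1852 lower at 6 h, and 1155 and 340 at 24 h. With quantile normalization it was 1436 and 372 at 24 h, and 1728 and 1530 at 6 h with the deposited table.

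Leaf sheath and stem pulvini that did not bend were compared over 1, 6 and 24 h together, with 11 and 9 samples. There were 15921 calls, 28.8% of the probes tested, 6396 higher in the leaf sheath and 9525 higher in the stem. P1000219192 was 23-fold higher in the leaf sheath, with an adjusted p of 3.8e-14, and P1000221673 20.4-fold higher in the stem, with 8.36e-18. The count ran from 12825 to 17347 with 1 library left out. Within session 1 there were 7089 calls and within session 2 there were 5779. Of the session 1 calls, 96.1% had the same direction in session 2.

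Many probes called between sides at 24 h were called in both tissues. Of the probes higher in the lower side, 2080 were called in both tissues, against 356.8 expected of independent lists. Of those higher in the upper side, 1905 were called in both, against 359.2 expected. There were 15 called in opposite directions, against 716 expected. At 6 h the tissues shared 355 probes higher in the lower and 304 higher in the upper side, against 47.8 and 67.4 expected, and 27 were opposite. At 1 h all 10 leaf sheath probes higher in the lower side, and 16 of 20 higher in the upper side, were called in the same direction in the stem. Across all probes the correlation of the side difference between tissues was 0.60 at 1 h, 0.39 at 6 h and 0.71 at 24 h. The lists of the tissues are not independent, since 25 of 31 arrays carried a sample of each tissue. All 5 leaf sheath side samples at 1 h, 4 of 7 at 6 h and 3 of 6 at 24 h shared an array with the same side of the stem at that time. With samples on shared arrays left out of 1 tissue, it was 0.47, 0.22 and 0.56. These values rest on few samples of that tissue: 1 lower and 1 upper stem sample at 1 h, 2 and 1 in the stem at 6 h, and 1 and 1 in the leaf sheath at 24 h.

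**Figure D3:**
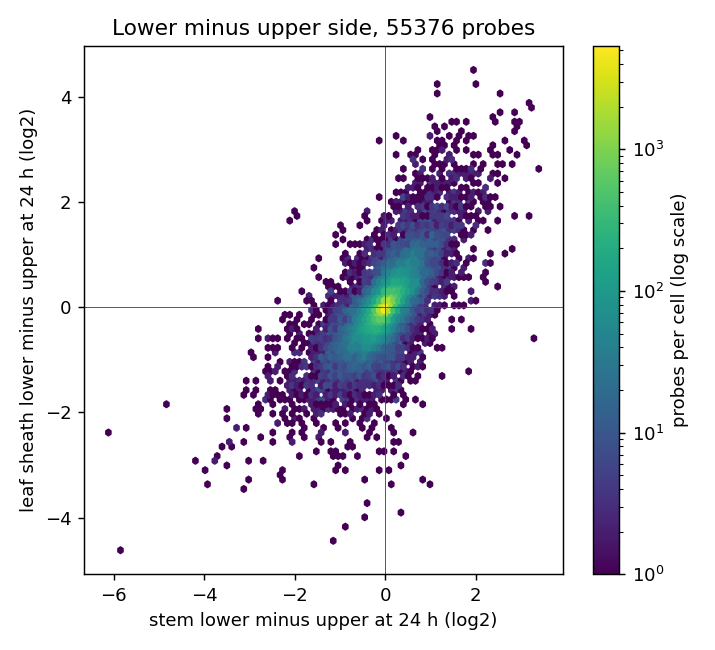
Log2 difference between the lower and upper side at 24 h in the stem (x axis) and in the leaf sheath (y axis) for 55376 probes; colour gives the number of probes per cell on a log scale. The correlation across probes was 0.71, and 15 probes were called in opposite directions.

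Where the tissues differed was tested by an interaction term. At 1 h 21 probes had a different side difference in leaf sheath and stem, 15 with a higher and 6 with a lower value in the leaf sheath. At 6 h there were 2089, 1172 higher and 917 lower, and at 24 h there were 469, 227 higher and 242 lower. Among the 24 h probes was P1000227495, 9.94-fold higher in the stem lower side, whose log2 difference was −0.56 in the leaf sheath. The 1 h count was 2, 11 and 8 without leaf sheath lower replicates 1 and 2 and upper replicate 2. It was 6, 115 and 33 without stem lower replicates 1, 2 and 4, and 11, 7 and 13 without stem upper replicates 1, 2 and 4. The 6 h count was 1143, 1170, 1228, 1089 and 854 without leaf sheath lower replicates 2 and 4, leaf sheath upper replicate 2, stem lower replicate 1 and stem upper replicate 2. At 24 h it was 150 without leaf sheath lower replicate 3, 231 and 308 without leaf sheath upper replicates 3 and 2, 87 without stem lower replicate 3, and 193 and 205 without stem upper replicates 2 and 3. Within session 1 limma made 24, 1386 and 0 calls, the 0 with 2549 probes at an unadjusted p under 0.05, and within session 2 there were 4, 8 and 1. The 6 h split was 520 higher and 233 lower with the processed signal and 362 and 165 with the deposited table.

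The change of the side difference from 1 h to 24 h was tested in the same way. In the stem 3194 probes changed, 1650 upward and 1544 downward, and in the leaf sheath 3921 changed, 1992 upward and 1929 downward. P1000295830 and P1000219221, both higher in the stem lower side at 1 h, had log2 differences of −0.01 and 0.28 at 24 h, neither past the test. The stem count was 1618, 2096 and 1856 without lower 24 h replicate 4 and upper 24 h replicates 1 and 2. In the leaf sheath it was 849 without upper 1 h replicate 4. It was 2302, 2379 and 2174 without lower 1 h replicate 1, lower 24 h replicate 3 and upper 24 h replicate 3. Within session 1 the counts were 94 and 11, and within session 2 they were 86 and 13. The stem split was 1229 up and 1821 down with the processed signal and 795 and 1171 with the deposited table.

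**Figure D4:**
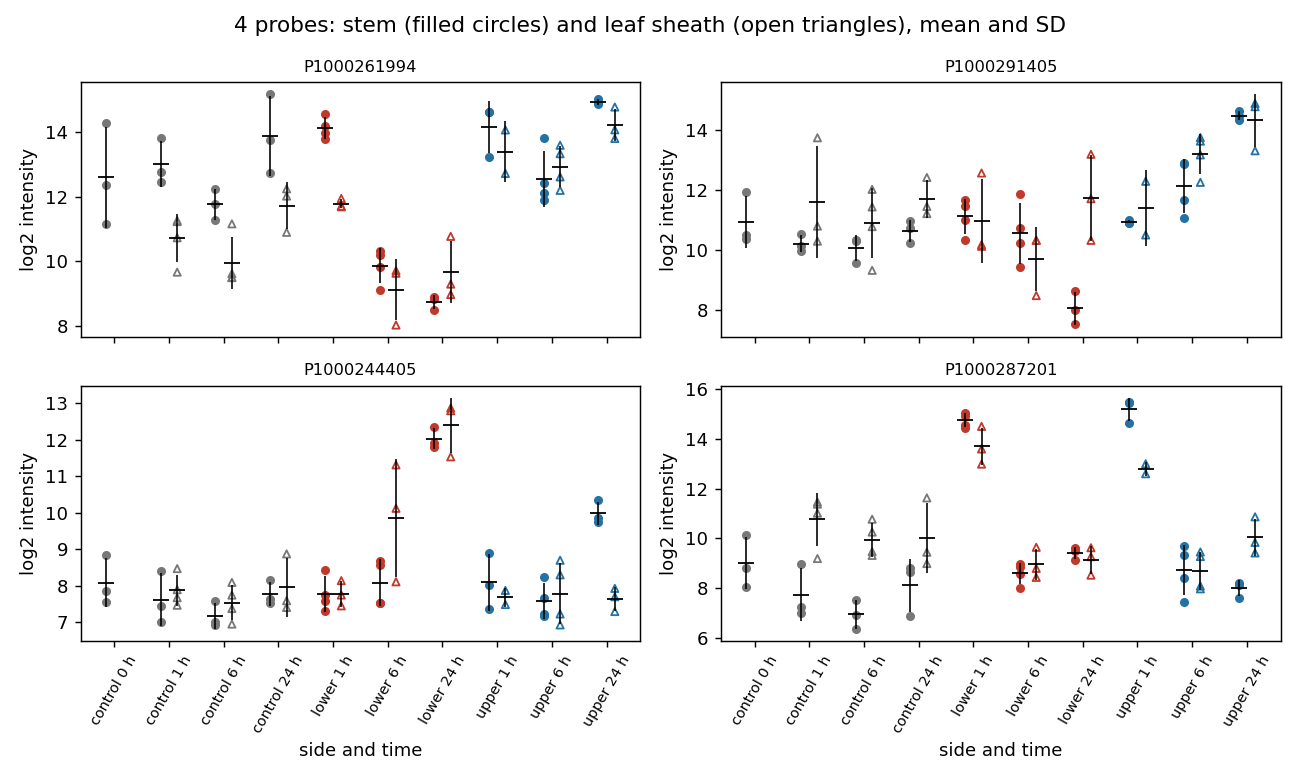
Log2 intensity of 4 probes in each sample by side and time, for stem (filled circles) and leaf sheath (open triangles), with the group mean and SD; the leaf sheath has no 0 h group. P1000261994 had a mean of 8.74 in the stem lower side at 24 h and 14.94 in the upper side, and P1000287201 a mean of 14.76 in the stem lower side at 1 h.

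The probes named at 24 h carry these sequences. P1000291405, lower in the stem lower side by a log2 difference of −6.17, has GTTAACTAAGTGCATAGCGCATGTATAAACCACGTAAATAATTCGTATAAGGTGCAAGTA. P1000261994, at −5.89 in the stem and −4.62 in the leaf sheath, has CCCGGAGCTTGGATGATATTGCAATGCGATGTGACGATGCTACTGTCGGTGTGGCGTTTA. P1000235184, at 3.45 in the stem, has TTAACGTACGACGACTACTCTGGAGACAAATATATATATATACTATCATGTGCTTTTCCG. P1000227495, at 3.31 in the stem, has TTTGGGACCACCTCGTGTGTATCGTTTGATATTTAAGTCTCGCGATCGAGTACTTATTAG. P1000310970, at 4.51 in the leaf sheath, has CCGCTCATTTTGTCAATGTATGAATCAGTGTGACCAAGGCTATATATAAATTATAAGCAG. P1000244405, at 4.29 in the leaf sheath, has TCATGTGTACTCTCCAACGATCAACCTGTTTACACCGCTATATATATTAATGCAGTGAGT. P1000271102, at −4.42 in the leaf sheath, has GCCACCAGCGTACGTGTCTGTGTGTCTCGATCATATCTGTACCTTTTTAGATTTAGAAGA.

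The authors' deposited table holds its own ratios, p values and q values against control. Of its 102961 rows, 8 had a q under 0.05 in each of stem lower 6 h, stem lower 24 h and stem upper 6 h, and none in the other comparisons that have a q column. Rows with a p under 0.05 ran from 4129 in leaf sheath upper 24 h to 13208 in stem lower 24 h. A q under 0.1 was listed for 280 rows in stem lower 6 h, 157 in stem lower 24 h, 83 in stem upper 6 h and 47 in stem upper 1 h. The table has no p or q for leaf sheath upper 1 h and 6 h, nor for lower over upper. The ratios correlated with ratios of group means of the deposited sample columns at 0.949 to 0.988 across rows, on the log2 scale. These values come from the authors' table and the calls above from the fit of the scanner files, so the counts are not on the same scale.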

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

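The tests of scan session, single libraries, sample number, normalization and time in this part were chosen after the results were seen; the tests of within-group spread at 1 h and of the dim control library were written before their values were seen.

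In groups of 4 samples, 39 checks found 4 samples far from the others, and chance alone gives about 1 in 20. P1000279134 measured 9.48 in leaf sheath control 1 h replicate 3, where the median of the others was 6.83. P1000261994 measured 11.16 in leaf sheath control 6 h replicate 4, beside 9.49. P1000298693 measured 7.999 in leaf sheath upper 6 h replicate 1, beside 7.86, and P1000265381 measured 9.30 in stem lower 6 h replicate 1, beside 8.03.

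A side difference that changed with time or tissue was found by the interaction test for 17 of 40 checks of named probes. These probes were picked as the largest side differences at 1 time in 1 tissue, so part of a smaller difference elsewhere comes from that choice. Between 1 h and 24 h in the stem, the log2 difference of lower minus upper moved by −4.86 for P1000295830, −4.00 for P1000219221, 3.15 for P1000225510 and 2.38 for P1000225231. It moved by −6.40 for P1000291405 and −5.91 for P1000261994. In the leaf sheath it moved by 5.11 for P1000211435, 1.77 for P1000214226, 4.30 for P1000310970, 4.12 for P1000244405 and −2.93 for P1000261994. The value for P1000211435 rests on 1 upper sample at 1 h, at 15.23. Leaf sheath less stem, the difference at 1 h was 2.22 for P1000225510 and 2.14 for P1000225231. At 6 h it was 3.39 for P1000252345 and 2.69 for P1000304780, and at 24 h −3.87 for P1000227495 and 3.77 for P1000291405.

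Between the leaf sheath sides 30 probes were called at 1 h, against 12350 at 24 h. Having 2 upper samples at 1 h was argued against as the whole cause, since the 24 h count stayed at 8169 or more with any 1 upper sample left out. A larger spread at 1 h was argued against too: the within-group SD was 1.04 times that at 24 h. The test of 24 h against 1 h called 3921 probes, consistent with a side difference that grew with time, although 849 were called without upper 1 h replicate 4. The 1 h upper samples both carried Cy3, as did all 3 lower samples, and came 1 from each scan session. The count at 1 h remains tied to few samples. At 24 h side and dye were partly tied: all 3 upper samples carried Cy3, while 1 lower sample carried Cy3 and 2 carried Cy5.

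The stem controls at 24 h and 0 h differed in 2182 probes, and the sessions agreed poorly on them, with r of 0.16 across probes. An average difference between sessions was argued against by 2279 calls with session as a block. Such a block cannot address a change with time that differs between sessions. A single library as the whole cause was argued against by 857 or more calls without any 1, though many calls depended on 1 library. Of the probes called higher in the stem, 41.1% moved the same way in leaf sheath controls on other arrays, and of those called lower, 63.0%. That comparison had 1 leaf sheath sample at 24 h and 2 at 1 h, and no 0 h sample. A change with time shared by both tissues and a change in the stem alone thus cannot be told apart. Given the r of 0.16, calls that would not repeat in other samples were not excluded either.

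Of the leaf sheath lower calls against control at 24 h, 66.8% were higher. Without the dim control library, replicate 1, the share was 62.1%. This lies above the bound set beforehand, past which the library would not be taken as the cause. It lies within 4.51 percentage points of that bound, the SD over left-out libraries. That margin was not part of the rule written beforehand and is not a standard error of the share. With it, an effect of that library and a real excess cannot be told apart. With the processed signal the share was 52.0%, so normalization may account for the excess. No biological explanation was tested.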

How the results depend on the processing

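The alternatives below were fixed before the data were examined, except those on scan session, which were chosen after the results were seen. The 33 gene lists and their estimated correlation could not be tried, for want of gene names. Named probes were not checked in the deposited table. No named probe changed direction under any other alternative in which it was tested. The counts within 1.5 times of the reported ones numbered 19 of 27 with quantile normalization, 14 of 27 with the processed signal, 19 of 27 with no filter, 19 of 27 with the slide as random block, 25 of 27 with no dye term, 19 of 23 with samples of the tissue alone, 9 of 27 with the deposited table and 26 of 27 with a replicate block. The others are given here as counts of calls. The cause of these changes was not tested, save that no filter tests more probes and that fits of fewer samples have less precision.

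Quantile normalization gave 1671 for stem lower minus upper at 6 h, 68 for leaf sheath lower minus upper at 1 h, and 2601 for leaf sheath lower minus control at 1 h. It also gave 494 and 208 for leaf sheath upper minus control at 1 and 6 h, 50 for stem control against 0 h at 1 h, and 398 and 925 for the difference of tissues at 1 and 6 h. The processed signal gave 559 and 1669 for stem lower minus upper at 1 and 6 h, 16 for leaf sheath lower minus upper at 1 h, and 3029 for leaf sheath lower minus control at 1 h. That signal also gave 3360 and 1982 for stem upper minus control at 6 and 24 h, 568, 163 and 823 for leaf sheath upper minus control at 1, 6 and 24 h, and 50 for stem control against 0 h at 1 h. That signal also gave 76, 753 and 171 for the difference of tissues at 1, 6 and 24 h. With no filter there were 5 for leaf sheath lower minus upper at 1 h, 1031 for leaf sheath lower minus control at 1 h, and 206 for leaf sheath upper minus control at 6 h. There were also 0 and 1408 for stem control against 0 h at 1 and 24 h, and 6, 1225 and 231 for the difference of tissues at 1, 6 and 24 h. Where limma called 0, 7185 probes had an unadjusted p under 0.05. The slide as random block gave 1448 for stem lower minus upper at 1 h, 60 for leaf sheath lower minus upper at 1 h, and 2857 and 3419 for leaf sheath lower minus control at 1 and 6 h. This block also gave 615 for leaf sheath upper minus control at 6 h, 11 for stem control against 0 h at 1 h, and 5 for the difference of tissues at 1 h. This block also gave 5296 for stem sides 24 h minus 1 h. With no dye term there were 0 for stem control against 0 h at 1 h, and 783 for the difference of tissues at 24 h. Where limma called 0, 5281 probes had an unadjusted p under 0.05. With samples of the tissue alone there were 1386 for stem lower minus upper at 6 h, 0 for stem control against 0 h at 1 h, and 78 for leaf sheath upper minus control at 6 h. They also gave 2577 for leaf sheath sides 24 h minus 1 h. Where limma called 0, 5062 probes had an unadjusted p under 0.05.

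The deposited table gave 499 and 1240 for stem lower minus upper at 1 and 6 h, 11 and 2543 for leaf sheath lower minus upper at 1 and 6 h, and 15419 and 1436 for leaf sheath lower minus control at 1 and 6 h. It gave 2243 and 957 for stem upper minus control at 6 and 24 h, 838, 76 and 405 for leaf sheath upper minus control at 1, 6 and 24 h, and 8 and 1097 for stem control against 0 h at 1 and 24 h. It gave 134, 527 and 145 for the difference of tissues at 1, 6 and 24 h, 1966 for stem sides 24 h minus 1 h, and 1970 for leaf sheath sides 24 h minus 1 h. Its values were fitted with the same model, but which scaling made them is not known, and 12 comparisons had a median log2 difference beyond 0.1 in it, up to 0.34. The processed signal had 1 such median, −0.12 for stem upper minus control at 1 h. With a replicate block the count that left the range was 24 for stem control 1 h against 0 h, and none of the other 26 did. Where the numbers were taken to pair the samples, the block changed no call of a named probe. Nor did it move any such count by over 1.5 times. Elsewhere P1000291252 alone lost its call. The block gives each replicate number 1 effect shared by all tissues and times. It therefore cannot show whether pairs within a tissue and time would change the calls.

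With scan session as a block, 26 of 27 counts were within 1.5 times, and that of stem control 1 h against 0 h was 4. Each session holds 1 or 2 samples per group. Within scan session 1 the counts were 183, 769 and 1034 for stem lower minus upper at 1, 6 and 24 h, 8, 438 and 171 for leaf sheath lower minus upper at 1, 6 and 24 h, and 1873, 4370 and 1310 for stem lower minus control at 1, 6 and 24 h. Session 1 also gave 82, 544 and 2201 for leaf sheath lower minus control at 1, 6 and 24 h, 3614, 809 and 16 for stem upper minus control at 1, 6 and 24 h, and 16, 31 and 5 for leaf sheath upper minus control at 1, 6 and 24 h. Session 1 also gave 0, 523 and 16 for stem control against 0 h at 1, 6 and 24 h, 7089 for leaf sheath minus stem control, and 1386 and 0 for the difference of tissues at 6 and 24 h. Session 1 also gave 94 for stem sides 24 h minus 1 h, and 11 for leaf sheath sides 24 h minus 1 h. Where limma called 0, 1727 and 2549 probes had an unadjusted p under 0.05. Within scan session 2 they were 73, 13 and 129 for stem lower minus upper at 1, 6 and 24 h, 18, 907 and 4692 for leaf sheath lower minus upper at 1, 6 and 24 h, and 1760, 103 and 11788 for stem lower minus control at 1, 6 and 24 h. Session 2 also gave 14, 243 and 2877 for leaf sheath lower minus control at 1, 6 and 24 h, 868, 0 and 63 for stem upper minus control at 1, 6 and 24 h, and 595, 2 and 184 for leaf sheath upper minus control at 1, 6 and 24 h. Session 2 also gave 123 and 2 for stem control against 0 h at 6 and 24 h, 5779 for leaf sheath minus stem control, and 4, 8 and 1 for the difference of tissues at 1, 6 and 24 h. Session 2 also gave 86 for stem sides 24 h minus 1 h, and 13 for leaf sheath sides 24 h minus 1 h. Where limma called 0, 3520 probes had an unadjusted p under 0.05.

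With each replicate left out in turn, counts ran from 492 to 1073 at 1 h, 1465 to 2746 at 6 h and 3309 to 6846 at 24 h for stem lower minus upper, and from 4 to 58 at 1 h, 1855 to 4766 at 6 h and 8169 to 11015 at 24 h for leaf sheath lower minus upper. They ran from 5427 to 10153 at 1 h, 5244 to 7918 at 6 h and 9459 to 19279 at 24 h for stem lower minus control, and from 468 to 1748 at 1 h, 656 to 2508 at 6 h and 5381 to 7888 at 24 h for leaf sheath lower minus control. Ranges were 5422 to 7300 at 1 h, 2564 to 5200 at 6 h and 1461 to 3758 at 24 h for stem upper minus control, and from 52 to 2082 at 1 h, 86 to 454 at 6 h and 766 to 2115 at 24 h for leaf sheath upper minus control. They ran from 0 to 14 at 1 h, 1904 to 3442 at 6 h and 857 to 2089 at 24 h for stem control against 0 h, and from 12825 to 17347 for leaf sheath minus stem control. Ranges were 2 to 115 at 1 h, 854 to 2714 at 6 h and 87 to 615 at 24 h for the difference of tissues, and from 1618 to 3990 for stem sides 24 h minus 1 h. They ran from 849 to 4163 for leaf sheath sides 24 h minus 1 h. Of 219 such counts, 138 were within 1.5 times of the reported ones. Of the named probes, 344 of 384 such checks kept the call and 40 lost it. Named probes lost their call 2 times with quantile normalization, 6 with the processed signal, 7 with no filter, 1 with a replicate block, 3 with no dye term and 5 with samples of the tissue alone. They lost it 1 time with scan session as a block, 22 times within session 1 and 35 within session 2. Signal over background limits the dim probes: of 103680 probes, 55376 passed the filter.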

Other observations

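The tests of shared responses in this part, the bounds for splits and the comparison of tissues on other arrays were chosen after the results were seen.

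P1000287201 and P1000279134 rose on both sides of both tissues at 1 h. P1000287201 had log2 changes from control of 7.18 and 7.43 in the stem lower and upper sides and 3.12 and 2.15 in the leaf sheath. P1000279134 had 6.81 and 6.41 in the stem and 4.49 and 5.16 in the leaf sheath. At 24 h P1000279134 stood at 0.12 and 0.06 in the stem and −0.32 and 0.26 in the leaf sheath, none past the test. A candidate explanation is a response to laying the plant over that both sides share at 1 h. The covariance of the sides' differences from control was compared with that of simulated unchanged groups. At 1 h it was larger by 0.138 in the stem and 0.0498 in the leaf sheath. The simulated samples were independent, so part of such an excess may come from correlated lower and upper samples. In the stem the excess was 0.0890 at 6 h and 0.0762 at 24 h. That of the leaf sheath was −0.00231 at 6 h and 0.00300 at 24 h, where probes that move apart can cancel those that move together. The leaf sheath sides shared 325 higher and 115 lower calls at 24 h, against 162.1 and 20.4 expected of independent lists, and part of that excess may come from the shared controls. A shared response and none thus cannot be told apart in the leaf sheath at 24 h. The labels describe controls only as not bending, so touch, handling and gravity were not separated.

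Of the probes called between the stem sides at 24 h, 87.0% had the same direction in leaf sheath samples on other arrays. Those were 1 lower and 1 upper sample, so a side difference common to both tissues and a difference between those 2 samples cannot be told apart by this value. Of the probes called between the leaf sheath sides, 93.3% of 30 at 1 h and 67.9% of 4872 at 6 h had the same direction in stem samples on other arrays, 1 lower and 1 upper at 1 h and 2 and 1 at 6 h. Of the probes called higher in stem controls at 6 h against 0 h, 83.0% moved the same way in leaf sheath controls on other arrays, and of those called lower, 81.8%. These leaf sheath values rest on 1 sample at 6 h and 2 at 1 h, so a time course common to both tissues and a deviation of that sample cannot be told apart. Time of day was not given, so no daily rhythm was tested.

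Probes fell into classes by their name in the files. Of those named by a clone or protein accession 88.4% were tested, and of those 34.5% were called between leaf sheath sides at 24 h. Of those with the ID alone 49.5% were tested and 21.4% of those called. Of contig probes marked as reverse, 49.9% were tested and 19.6% of those called.

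Samples were also divided in other ways into groups of the same sizes. The real split alone gave as many calls, 1 of 35 splits and so a share under 0.05, for each of 3 comparisons whose numbers were not taken to pair the samples. These were stem lower minus control at 6 h, with 8574 calls and 4863 in the highest other split, stem upper minus control at 6 h, with 5405 and 2014, and leaf sheath upper minus control at 6 h, with 397 and 15. In stem lower minus control at 6 h 1 pair alone fell below 0.1, at r of 0.08 beside 0.42 and 0.24. The shares were not adjusted over the comparisons split, and their bounds were chosen after the results were seen, so chance was not excluded.

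Where the replicate numbers were taken to pair the samples, the real split was set against splits that part as many pairs. For leaf sheath minus stem control it alone gave as many calls in 1 of 100 of these, a share under 0.05, with 15921 and 9306 in the highest other. The same held for the difference of tissues at 24 h in 1 of 32 splits, with 469 and 109. Drawn splits that parted fewer pairs gave at most 6713 and 250 calls. For the difference of tissues at 6 h and the stem sides at 24 h less 1 h, lower and upper samples were taken as pairs. There the real split was set against splits that keep these pairs whole. The real split alone gave as many calls, in 1 of 35 splits with 2089 and 725, and in 1 of 30 with 3194 and 1400. In each test of a difference of side differences, the average difference of the tissues or times was taken out beforehand. The shares in this paragraph were not adjusted over comparisons either, so chance was not excluded. Splits that broke a pair gave at most 217 and 1540 calls there, in 98 and 97 of those drawn. In 6 other comparisons 8 splits parted as many pairs, too few for a share under 0.05. Among those 8, the real count and the highest other were 845 and 346 for stem lower minus upper at 1 h, 2627 and 349 at 6 h, and 4872 and 1795 for leaf sheath lower minus upper at 6 h. For lower minus control they were 9794 and 3289 in the stem at 1 h, and 1693 and 41 at 1 h and 2193 and 354 at 6 h in the leaf sheath. The other 27 splits of each put both samples of at least 1 pair in the same group. In the order given, the highest of them gave 971, 690, 1736, 6501, 1035 and 886 calls. For stem lower minus upper at 1 h, 3 of all 35 splits, the real one included, gave 845 calls or more, a share not under 0.05.

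With 3 samples against 3 there are 10 splits, too few for a share under 0.05. The real count and the highest other were 6421 and 554 for stem lower minus upper and 12350 and 12 for leaf sheath lower minus upper at 24 h. They were 19600 and 6332 for stem lower minus control, 8484 and 1646 for leaf sheath lower minus control, 3601 and 18 for stem upper minus control and 1985 and 87 for leaf sheath upper minus control at 24 h. For stem upper minus control at 1 h they were 8460 and 0. For stem controls against 0 h they were 4034 and 574 at 6 h and 2182 and 37 at 24 h. At 1 h 2 of 10 splits gave 2 or more calls, and the highest other gave 3. Comparisons that use the 2 leaf sheath upper samples at 1 h were not split.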
